A study of Oryza sativa with 12 samples.

How the data were processed

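Rice seedlings of the japonica cultivar Wuyunjing 7 grew in hydroponics with 1.25 mM ammonium nitrate, were kept 1 week without nitrogen, and then spent 96 h on ammonium nitrate, ammonium alone, nitrate alone or no nitrogen. The sulfate and chloride of the solutions differed between treatments too. Per the labels, RNA of roots and of shoots was amplified, labelled with Cy3 or Cy5 and hybridised to Agilent 60-mer 2-colour arrays, with 2 biological replicates per treatment. Replicate 1 of each group carries the treated RNA in Cy5 and replicate 2 in Cy3. The deposited values are taken to be a log10 ratio of the 2 channels for each feature. Their scale is read from the values: 6 values on 3 arrays lie at exactly -2 or 2, the limits of a log10 ratio of this scanner software. Background correction and dye normalization are not stated, and no scanner files were used here. Array medians of the log10 ratio lay between -0.0031 and 0.0013, so the values were centred by array as received and were not centred again. No value was missing, and 187 to 349 values per array were exactly 0.

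The labels hold 3 contradictions. The array of shoots without nitrogen, replicate 1, names ammonium nitrate RNA in both channels while its title says no nitrogen, and its Cy5 channel was taken as the treated one. The tissue field says roots for the shoot arrays as well, and tissue was taken from titles and sources. The time of full nutrition is given as 12 days in one place and as 2 weeks in another. The number of control extracts is not stated. Each group is therefore tested as a ratio against 0.

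The table holds 22575 features on 12 arrays, set out in 215 array rows and 105 columns. Of these, 17839 match 1 gene, 21 match several and 4715 match none. Tests used the 17860 with a gene, which stand for 15798 genes where 1 gene was given. Only 2411 of them (13.5%, 2110 genes) have a symbol of their own in the gene table, and the rest carry a locus identifier, so named genes and lists come from that part. Counts are of probes.

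Ratios were converted to log2 and the replicate 2 arrays turned to treated over control. The rule set before the data were examined left a direction unsettled if groups disagreed in the sign of the correlation between their 2 arrays. They disagreed: over all features r as deposited was 0.185, 0.446 and -0.132 in roots on ammonium, on nitrate and without nitrogen, and 0.755, 0.646 and 0.139 in shoots. Turning every replicate 2 array was decided after the values were seen. Its basis is the dyes in the labels, and that features without a gene, taken to carry less treatment signal, kept their sign in both orientations (r from 0.609 to 0.918). The mean over the 2 orientations is the treatment part and their difference the dye part. The dye part correlated from 0.698 to 0.822 between pairs of the 4 groups with nitrogen, across tissues too, and from 0.074 to 0.377 in pairs with a group without nitrogen. The direction of treated over control is therefore called likely. Replicate correlations cannot settle the sign of the whole table.

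The model was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per group over all 12 arrays, no block, and Benjamini-Hochberg adjustment per comparison with calls at an adjusted p under 0.05. This leaves 6 residual degrees of freedom, 1.95 prior ones and a median probe SD of 0.205 on the log2 scale. The 6 groups, 2 contrasts of ammonium minus nitrate and 3 contrasts of roots minus shoots were fixed before the data were examined, as were the test, the alternatives and the rule for naming genes. Whether replicate numbers pair the arrays was checked on the dye part, which correlated between groups of a tissue from 0.153 to 0.822. The replicate number equals the dye orientation, so a replicate block takes up dye, place on the array, shared control and pairing together. Its values are given beside the results.

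The naming rule takes, per comparison, the 8 highest and 8 lowest ratios among passing probes with the same sign on both arrays and a symbol, filled up by lowest p where fewer pass. It adds up to 4 members of largest ratio from each list that passes or has 2 or more calls, always including nitrate and ammonium transport, nitrate reduction and ammonium assimilation. For contrasts it takes 3 in each direction. The probe of smallest p names a gene, and other probes are given where they differ. YSL14 and JAZ3 at the array edge, and the genes under other observations, were chosen after their values were seen.

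There were 34 gene lists. The themes of 25 were fixed before the data were examined, but as the annotation holds few descriptions, the symbols that fill them were written after the counts of calls had been seen. A further 9 lists (type-A response regulators, potassium transporters, urea and ureide breakdown, jasmonate ZIM-domain proteins, Aux/IAA proteins, fermentation, DNA replication, cellulose synthases, glycolate oxidase and catalase) were added then, before any gene's or list's result. The 27 lists with at least 5 probes were tested in the 6 groups with camera at a preset correlation between genes of 0.01, adjusted over all 162 tests, and again with an estimated correlation. Counts adjusted over the list alone use limma p-values adjusted within the list. The other 7 lists are described by their counts.

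The fit was tested on simulated data. Of 100 probes given a log2 change of 1, 62 were recovered in roots on ammonium and 61 in shoots on nitrate, and of 100 given 2, 87 and 88, all in the right direction, with 3 and 0 unchanged probes called. Of 10 lists shifted by 0.5, 10 were called, and 0 of 30 unchanged lists. These lists held random probes, and the noise was drawn independently for each probe and array. False list calls from genes that vary together could therefore not appear in this check.

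Alternatives fixed before the data were examined were centring each array, scaling arrays to one median absolute deviation, a replicate block common to both tissues or within each tissue, the 6 arrays of a tissue alone, robust eBayes, leaving out probes with an exact 0 on any array (448), a criterion of 2-fold on both replicates in place of the test, each array left out in turn, and for lists the estimated correlation, a common block and the mean of a gene's probes. Chosen after seeing the data were all 22575 features, leaving out the 4200 features of array rows 1 to 40 (3297 with a gene), keeping values as deposited with no array turned, and lists with a block within tissue or each array left out. In the report the replicate block is the one within tissue unless the common one is named. Overlap between treatments was set against values simulated for unchanged groups that share a control. The simulation used 1 spread per probe, pooled over both tissues and including the low edge of 1 shoot array. It gave control and treated RNA equal shares of that spread.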

Results

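Rice seedlings in hydroponics were kept 1 week without nitrogen. They then spent 96 h on ammonium nitrate, ammonium alone, nitrate alone or no nitrogen before mRNA was measured in roots and shoots. Each array set a treated tissue against the same tissue on ammonium nitrate, the control, in 2 dyes. There were 6 groups, 3 treatments in 2 tissues, with 2 arrays each, from biological replicates with the dyes exchanged. The comparisons ask which genes respond when 1 form of nitrogen is left out, and which when nitrogen stays absent. All values are log2 ratios of treated over control, a likely direction that the labels do not settle. If the deposited ratios run the other way, every rise below is a fall. The p-values measure only the spread between these samples, and the control's own spread enters only through the 2 replicates. The number of arrays limits the precision.

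Genes for a pathogenesis-related protein, a germin-like protein and a urea transporter rose in roots on ammonium alone relative to roots on ammonium nitrate. The largest rise was in PBZ1 (LOC4352491), a pathogenesis-related protein of the PR-10 family, at a log2 ratio of 4.83 (SE 0.0766, n = 2 arrays, adjusted p = 9e-08). GLP2 (LOC4344846), a germin-like protein, reached 3.67 (SE 0.19, adjusted p = 2.33e-05), and DUR3 (LOC4349520), a high-affinity urea transporter, 3.12 (SE 0.11, adjusted p = 4.73e-06). The chitinase RC7 (LOC4338718) rose by 2.84, the metallothioneins MT1B (LOC4332487) and MT2B (LOC4326409) by 2.80 and 2.36, the ABC transporter ABCG43 (LOC4343412) by 2.58 and the phosphate transporter PTH1-2 (LOC4331637) by 2.54. The lowest ratios belonged to the formin FH15 (LOC4347588, -1.51), the calmodulin-like CML1 (LOC4327351, -1.31), the glutathione transferase GST1 (LOC4334347, -1.3), the tonoplast aquaporin TIP2-1 (LOC4330207, -1.22), OsCASP1 (LOC4337453, -1.06), the plasma membrane aquaporin PIP2-6 (LOC4335226, -1.06), DTH7 (LOC4344399, -1.05) and FIB (LOC4325198, -1.03), an enzyme of auxin synthesis. A second probe of MT2B read 0.04 and a second probe of DTH7 read -0.12.

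Among the nitrogen genes of these roots, NRT2.3 (LOC4324249) and NRT2.2 (LOC4328052), both high-affinity nitrate transporters, rose by 1.74 and 1.32, while NAR2.2 (LOC4336175) stood at 0.06 (adjusted p = 0.903). That made 2 of 3 probes of nitrate transport, the same number adjusted over the list alone. The nitrate reductase NIA1 (LOC4345795) stood at -0.23 (adjusted p = 0.488). Of 8 probes of ammonium transporters 4 rose and none fell, or 5 adjusted over the list alone. The list shifted upward (camera adjusted p = 0.000247, adjusted p = 0.101 with an estimated correlation). AMT1-2 (LOC4330008) rose by 2.29, AMT3-2 (LOC4334717) by 1.59 and AMT1-1 (LOC4336365) by 1.16, with a second AMT1-1 probe at 0.00, and AMT3-3 (LOC4329628) at 1.49 did not pass (adjusted p = 0.2). Of 8 probes of ammonium assimilation 1 rose and 1 fell, also adjusted over the list alone, both glutamate dehydrogenases. GDH2 (LOC4336554) was at 0.91, its second probe at 0.23, and GDH1 (LOC4334405) at -0.62.

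Of 26 iron probes 6 rose, also adjusted over the list alone. The list's adjusted p was 0.0495 (0.068 with the replicate block, 0.0583 with the mean of a gene's probes, 0.0984 without replicate 2, 0.0515 to 0.0713 without any 1 of the nitrate root, ammonium shoot or no-nitrogen arrays, adjusted p = 0.166 with an estimated correlation). The iron-phytosiderophore transporter YSL15 (LOC9268232) rose by 1.41, YSL16 (LOC4336546) by 0.86, the iron transporter IRT1 (LOC4333669) by 0.80 and the regulator IRO3 (LOC4332972) by 0.79. Of 19 probes of phosphate starvation genes 6 rose, also adjusted over the list alone. Among them were the sensors SPX2 (LOC4328654, 1.18) and SPX4 (LOC4334647, 0.64, second probe 0.06) and the transporters PHT1-8 (LOC4348741, 1.05, second probe 0.10) and PHT1-2 (LOC4335115, 1.03). The list, which does not hold the PTH1-2 named above, did not pass (adjusted p = 0.0546). Of 7 probes of senescence and autophagy 2 rose, or 3 adjusted over the list alone: SGR (LOC4347672), which starts chlorophyll breakdown, at 2.1 and OSL2 (LOC4336983) at 1.28 (camera adjusted p = 0.0251, adjusted p = 0.163 with an estimated correlation). Of 20 phenylpropanoid probes 6 rose, also adjusted over the list alone, led by PAL06 (LOC4330040, 2.03), a phenylalanine ammonia-lyase, and CAD6 (LOC4335223, 1.58). Their list's adjusted p was 0.017 (0.0582 without replicate 2, adjusted p = 0.151 with an estimated correlation). Of 15 probes of pathogenesis-related proteins 5 rose, or 6 adjusted over the list alone, and besides PBZ1 and RC7 these held the chitinases RC24 (LOC4342115, 2.01) and Cht8 (LOC4349267, 1.12) (camera adjusted p = 0.00524, adjusted p = 0.185 with an estimated correlation). Of 14 jasmonate ZIM-domain repressors 5 probes rose, also adjusted over the list alone, with JAZ12 (LOC4348533) at 2.17, JAZ11 (LOC4331833) at 1.76 and JAZ9 (LOC4331832) at 0.97 (camera adjusted p = 0.00312, adjusted p = 0.101 with an estimated correlation).

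Of 26 aquaporin probes 5 fell and none rose in roots on ammonium, against 7 down and 2 up adjusted over the list alone and 7 down and 1 up with the replicate block. The list's adjusted p was 0.0299 (0.0567 with the block within tissue, 0.0404 with the common block, 0.0762 with the mean of a gene's probes, 0.0582 without replicate 2, adjusted p = 0.151 with an estimated correlation). Beside TIP2-1 and PIP2-6, the silicon channel Lsi6 (LOC4340558) fell by 0.83, with other probes at -0.86 and 0.01. Of 17 probes of cyclins and a centromere histone 3 fell, or 5 adjusted over the list alone and 6 with the replicate block, among them CYCD3-2 (LOC4346394, -0.86) and CYCB2-2 (LOC4342121, -0.59) (camera adjusted p = 0.000778, adjusted p = 0.127 with an estimated correlation). The 21 DNA replication probes had a median of -0.27 and shifted downward (camera adjusted p = 0.00233, adjusted p = 0.101 with an estimated correlation), with 0 of them called by limma over all genes, 0 adjusted over the list alone and 5 down with the replicate block. RPA1B (LOC4332052) stood at -0.60 (adjusted p = 0.0688) and MCM5 (LOC4331016) at -0.52 (adjusted p = 0.287). Over all genes, 1425 probes rose and 507 fell of 17860 tested, and 2230 rose and 1225 fell with the replicate block. Without replicate 1 of this group 688 were called (598 up, 90 down) and without replicate 2, 768 (632 up, 136 down). GST1, OsCASP1 and DTH7 lost their calls without either array (adjusted p from 0.0525 to 0.282). Calls of list members that ended without replicate 1, with the value then, were those of GDH2 (1.08), OSL2 (1.59), CYCD3-2 (-1.03), CYCB2-2 (-0.49), YSL16 (1.00), JAZ11 (1.83), JAZ9 (0.68), GDH1 (-0.55), SPX4 (0.54), PAL06 (1.77), Cht8 (0.94) and Lsi6 (-0.70). Without replicate 2 they were those of GDH2 (0.73), OSL2 (0.98), CYCD3-2 (-0.69), CYCB2-2 (-0.70), YSL16 (0.72), JAZ11 (1.70) and PHT1-8 (0.88). With the root arrays alone DTH7 and CYCB2-2 lost their call. OsCASP1, AMT3-2, Lsi6, PHT1-2, GDH2 and RC24 are read in array rows 1 to 40, where the pooled spread includes the low readings of 1 shoot array.

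The urea transporter DUR3 and the nitrate transporters NRT2.2 and NRT2.3 rose in roots on nitrate alone relative to roots on ammonium nitrate. DUR3 rose most, by 3.26 (SE 0.11, n = 2 arrays, adjusted p = 1.2e-05). NRT2.2 rose by 2.56 (SE 0.172, adjusted p = 0.000119) and NRT2.3 by 2.25 (SE 0.0844, adjusted p = 1.2e-05), which again made 2 of 3 nitrate transport probes, also adjusted over the list alone, with NAR2.2 at -0.03 (adjusted p = 0.998). NIA1 rose by 1.43 (SE 0.149, adjusted p = 0.000871) on 1 of its 2 probes, the other reading -0.11. Other high values were those of AMT3-3 (2.71), MT1B (2.42), the laccase LAC10 (LOC4332400, 2.13), SGR (2.05) and IRT1 (2.03). At the low end stood TIP2-1 (-1.76), CML1 (-1.68), the auxin conjugate hydrolase ILL3 (LOC4334707, -1.64), Lsi6 (-1.57, other probes -1.59 and -0.05), PIP2-6 (-1.51), the tonoplast aquaporin TIP2-2 (LOC4340941, -1.51), OsCASP1 (-1.46) and the trehalose-phosphate phosphatase TPP3 (LOC4343959, -1.41).

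Of the 8 ammonium transporter probes 5 rose in roots on nitrate, or 6 adjusted over the list alone, with AMT3-2 at 1.96, AMT2-2 (LOC4327434) at 1.14 and AMT1-2 at 0.85 (camera adjusted p = 0.000363, adjusted p = 0.101 with an estimated correlation). Among 8 probes of ammonium assimilation GDH1 (-1.18) and the ferredoxin-dependent glutamate synthase Fd-GOGAT (LOC4344164, -0.46) fell, the same 2 adjusted over the list alone. The list did not pass (adjusted p = 0.051, adjusted p = 0.185 with an estimated correlation), but did without replicate 1 or 2 of the nitrate shoots (0.0479 and 0.0478). Iron genes rose at 5 of 26 probes, also adjusted over the list alone, including YSL15 (1.43), YSL16 (1.06) and IRO3 (0.58), while the list's median was -0.06, its mean 0.17 and its adjusted p 0.315. Of 7 senescence probes 2 rose, or 3 adjusted over the list alone, SGR and OSL2 (1.10, adjusted p = 0.0459 and 0.0565 with the replicate block), with a list adjusted p of 0.0299 (0.0938 without replicate 1, adjusted p = 0.166 with an estimated correlation). Of 20 phenylpropanoid probes 3 rose, also adjusted over the list alone, and 6 with the replicate block, among them PAL06 (1.39) and CAD6 (1.23). Their list's adjusted p was 0.0458 (0.214 without replicate 2, 0.0502 and 0.0548 without replicate 1 or 2 of the roots without nitrogen, 0.0527 without array rows 1 to 40, adjusted p = 0.166 with an estimated correlation). Chitinases RC7 (1.63) and RC24 (0.91) and PBZ1 (1.33) were the 3 of 15 pathogenesis-related probes that rose, also adjusted over the list alone. Their list did not pass (adjusted p = 0.051, adjusted p = 0.301 with an estimated correlation), but did without replicate 1 (0.0234) or replicate 1 of the ammonium roots (0.0476). SPX2 (1.03), SPX4 (0.39, second probe 0.00) and PHT1-2 (1.45) were among 4 of 19 phosphate starvation probes that rose, or 5 adjusted over the list alone (camera adjusted p = 0.361).

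Aquaporins were the group that fell most often in roots on nitrate: 10 of 26 probes fell and 1 rose, against 10 and 2 adjusted over the list alone or with the replicate block (camera adjusted p = 0.000319, adjusted p = 0.101 with an estimated correlation). Of 30 probes of starch, sucrose and trehalose metabolism 6 fell and 1 rose, also adjusted over the list alone, and 7 fell and 3 rose with the replicate block. That list's adjusted p was 0.0305 (0.0577 with the block common to both tissues, 0.0798 with the mean of a gene's probes, 0.23 without replicate 1, adjusted p = 0.203 with an estimated correlation). Beside TPP3, the cell wall invertase CIN2 (LOC4335790) fell by 1.22 and the starch synthase SSII-2 (LOC4330709) by 0.90, with its second probe at -0.73, and CIN4 (LOC4324001) rose by 1.01. Of 17 probes of cyclins and a centromere histone 1 fell, also adjusted over the list alone, or 2 with the replicate block, CYCD5-3 (LOC4331985, -0.40), with a list adjusted p of 0.0486 (0.0503 with the mean of a gene's probes, 0.0882 without replicate 1, 0.126 without replicate 2, 0.0502 and 0.0548 without replicate 1 or 2 of the roots without nitrogen, 0.0527 without array rows 1 to 40, adjusted p = 0.246 with an estimated correlation). Over all genes 984 probes rose and 498 fell, and 1714 rose and 979 fell with the replicate block. Without replicate 1 of this group 453 were called (311 up, 142 down) and without replicate 2, 528 (367 up, 161 down). AMT3-3 lost its call without replicate 1 (adjusted p = 0.416) and without replicate 2 (adjusted p = 0.0706), and TIP2-2 without replicate 1 (adjusted p = 0.136). Calls of list members that ended without replicate 1 were those of SPX4 (0.31), OSL2 (0.96), PAL06 (1.12), AMT2-2 (0.72), Fd-GOGAT (-0.54), CYCD5-3 (-0.48), YSL16 (1.17), IRO3 (0.59) and SPX2 (0.79). Without replicate 2 they were those of SPX4 (0.48), OSL2 (1.25), PAL06 (1.67), RC24 (0.56), Fd-GOGAT (-0.37), CYCD5-3 (-0.32), YSL16 (0.95) and IRO3 (0.58). With the root arrays alone AMT3-3, AMT2-2, Fd-GOGAT, SPX4, OSL2, RC24 and CYCD5-3 lost their call. The responding NIA1 probe and those of AMT3-2, Lsi6, TIP2-2, OsCASP1, PHT1-2 and RC24 lie in array rows 1 to 40, where the pooled spread includes the low readings of 1 shoot array.

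Tested against each other, ammonium and nitrate left roots with different mRNA levels of single genes, and no list was tested on this difference. PBZ1 was higher on ammonium than on nitrate by 3.51 (SE 0.108, adjusted p = 1.78e-05), with 4.83 against 1.33 relative to the control. The ABC transporters ABCG36 (LOC4327728) and ABCG43 were higher on ammonium by 2.36 and 2.1. NIA1 was lower on ammonium by a difference of -1.65 (adjusted p = 0.0117, its second probe at 0.00), and IRT1 by -1.23 (adjusted p = 0.00357). These were the only genes with a name of their own to be lower on ammonium, among 5 such probes in all. The contrast called 125 probes higher and 5 lower, and 305 and 42 with the replicate block. Leaving out replicate 1 or 2 of the ammonium roots left 54 and 60 calls, and leaving out replicate 1 or 2 of the nitrate roots 57 and 61, with 2 to 4 of them lower. Leaving out any 1 of the 6 shoot arrays left 3 lower. ABCG36 and NIA1 are read in array rows 1 to 40, and with the root arrays fitted alone NIA1, ABCG36 and ABCG43 lost their call. ABCG36 also lost it without ammonium replicate 2 (2.11) or nitrate replicate 1 (2.12), ABCG43 without nitrate replicate 2 (1.92), and NIA1 without ammonium replicate 1 (-1.49) or 2 (-1.82) or nitrate replicate 2 (-1.46).

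Roots kept without nitrogen showed the largest responses. PBZ1 rose by 5.44 (SE 0.0766, n = 2 arrays, adjusted p = 3.52e-08), a class III peroxidase (LOC4344277) by 4.93 (SE 0.202, adjusted p = 3.24e-06) and ICL (LOC4343441), the isocitrate lyase of the glyoxylate cycle, by 4.33 (SE 0.231, adjusted p = 1.12e-05). The nicotianamine synthases NAS2 (LOC4332607) and NAS1 (LOC4332608), which make the chelator of iron in plants, fell by 4.54 (SE 0.429, adjusted p = 0.000224) and 4.33 (SE 0.299, adjusted p = 4.36e-05). Further rises were those of the methyltransferase ROMT-17 (LOC4345935, 4.18, second probe -0.01), the lectin salT (LOC4326471, 3.95), JAZ12 (3.56), JAZ11 (3.45) and TBT2 (LOC4351010, 3.44), a tryptamine benzoyltransferase. Further falls were those of ILL3 (-4.19), TIP2-1 (-3.30), Lsi6 (-2.96, other probes -2.96 and -0.26), OsCASP1 (-2.73), the peroxidase PRX74 (LOC4339222, -2.73) and the methylthioribose kinase MTK1 (LOC4337347, -2.69).

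NRT2.3 rose by 1.79 in these roots while NRT2.2 stood at 0.17 (adjusted p = 0.691), so that 1 of 3 nitrate transport probes rose, also adjusted over the list alone, and NIA1 stood at 0.15 (adjusted p = 0.673). Of 8 ammonium transporter probes 3 rose and 1 fell, or 5 and 1 adjusted over the list alone. AMT3-2 rose by 1.65 and AMT2-1 (LOC4339064) by 1.05, AMT1-2 fell by 1.11, and the list did not pass (adjusted p = 0.155). Of 8 probes of ammonium assimilation 2 rose, both of GDH2 (0.82 and 1.28), and GDH1 fell by 1.12, against 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.714). Among 11 probes of urea, ureide and arginine breakdown DUR3 (2.01), the allantoinase ALN (LOC4337428, 1.00) and the ureidoglycolate hydrolase UAH (LOC4352706, 0.73) rose, or 4 probes adjusted over the list alone. That list's adjusted p was 0.0464 (0.0501 with the mean of a gene's probes, 0.082 without replicate 2, 0.05 to 0.0555 without any 1 of the nitrate root arrays, the ammonium shoot arrays or the shoot arrays without nitrogen, adjusted p = 0.203 with an estimated correlation).

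Of 26 iron probes 10 fell and 3 rose, or 11 and 3 adjusted over the list alone. Beside NAS1 and NAS2, IRT1 fell by 2.23 and IDI2 (LOC4350083) by 1.41, with a second IDI2 probe at -0.75 (camera adjusted p = 0.00099, adjusted p = 0.101 with an estimated correlation). Jasmonate ZIM-domain repressors rose at 8 of 14 probes, or 10 adjusted over the list alone, with JAZ9 at 1.34 and JAZ10 (LOC4331834) at 1.22 (camera adjusted p = 1.02e-06, adjusted p = 0.101 with an estimated correlation). Of 20 phenylpropanoid probes 8 rose, also adjusted over the list alone, led by PAL06 (3.40), the ligase 4CL3 (LOC4328485, 2.52), CAD6 (2.39) and CAD8A (LOC4346988, 1.75) (camera adjusted p = 0.00483, adjusted p = 0.101 with an estimated correlation). Of 15 pathogenesis-related probes 7 rose, also adjusted over the list alone, with RC24 at 3.33, RC7 at 1.48 and Cht5 (LOC4336265) at 1.37 beside PBZ1 (camera adjusted p = 0.00233, adjusted p = 0.166 with an estimated correlation). SGR (2.69) and the chlorophyll b reductase NYC1 (LOC4327178, 2.45) were the 2 of 7 senescence probes that rose, or 4 adjusted over the list alone (camera adjusted p = 0.0202, adjusted p = 0.155 with an estimated correlation). Of 19 phosphate starvation probes 7 rose, also adjusted over the list alone, among them SPX2 (1.28), PHT1-8 (1.2, second probe -0.04), PHT1-2 (1.18) and PHO1-3 (LOC4341088, 1.07), in a list that did not pass (adjusted p = 0.111).

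Aquaporins fell at 8 of 26 probes and rose at 1 in roots without nitrogen, or 10 and 3 adjusted over the list alone and 11 and 2 with the replicate block. TIP2-2 fell by 1.62 and TIP4-1 (LOC4338163) rose by 1.29 (camera adjusted p = 0.00483, 0.0506 with the mean of a gene's probes, adjusted p = 0.101 with an estimated correlation). The 21 DNA replication probes had a median of -0.15 with 0 called by limma over all genes, 0 adjusted over the list alone and 3 down with the replicate block. Their list's adjusted p was 0.0251 (0.0746 without replicate 2, adjusted p = 0.151 with an estimated correlation). The lists of the light reactions and of chlorophyll synthesis, at medians of -0.31 and -0.12, did not pass (adjusted p of 0.119 and 0.0641, adjusted p = 0.561 and 0.185 with an estimated correlation), nor with the common block (0.135 and 0.06). They passed with the block within tissue (0.0336 and 0.0486), which was chosen for lists after the data were seen, and chlorophyll synthesis without replicate 1 (0.0366). Of these 12 and 16 probes, 2 and 1 fell, also adjusted over the list alone except that 1 light reaction probe then rose, and with the replicate block 6 and 4 fell and 1 in each rose. One of those that fell was petC (LOC4343570, -0.74), of the cytochrome b6f complex. Over all genes 1908 probes rose and 847 fell, and 2742 rose and 1587 fell with the replicate block. Without replicate 1 of this group 1520 were called (1172 up, 348 down) and without replicate 2, 1296 (870 up, 426 down). MTK1 lost its call without either array (adjusted p = 0.0744 and 0.0519). So did 4CL3 (2.44 and 2.60), Cht5 (1.73 and 1.00) and petC (-0.79 and -0.69). TIP2-2 (-1.40), TIP4-1 (1.23) and the lower GDH2 probe (0.70) lost it without replicate 1, and PHO1-3 (0.62) and UAH (0.46) without replicate 2. With the root arrays alone PHO1-3 and Cht5 lost it. MTK1, Lsi6, OsCASP1, TIP2-2, AMT3-2, AMT2-1, 4CL3, PHT1-2, RC24 and the higher GDH2 probe are read in array rows 1 to 40, where the pooled spread includes the low readings of 1 shoot array.

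Across root probes the responses to the 3 treatments ran together. Ratios on ammonium and on nitrate correlated with r = 0.725 over genes, ammonium and no nitrogen with 0.66, and nitrate and no nitrogen with 0.586. Genes are not independent replicates, and the treatments share their control, for which unchanged groups simulated gave r from 0.503 to 0.505. The covariances were 0.11, 0.142 and 0.109 against simulated 0.0387, 0.0384 and 0.0385. Between arrays of opposite replicate number r was 0.325, 0.538 and 0.449. Such arrays also carry the dye part with opposite sign, which lowers these values where the dye part is shared. Among called probes 589 rose and 160 fell in all 3 treatments. Ammonium and nitrate shared 780 rising and 235 falling probes, where independent lists would share 78.5 and 14.1. Ammonium and no nitrogen shared 964 and 250 against 152 and 24.0, and nitrate and no nitrogen 677 and 281 against 105 and 23.6. The independent counts take no account of the shared control.

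**Figure D1:**
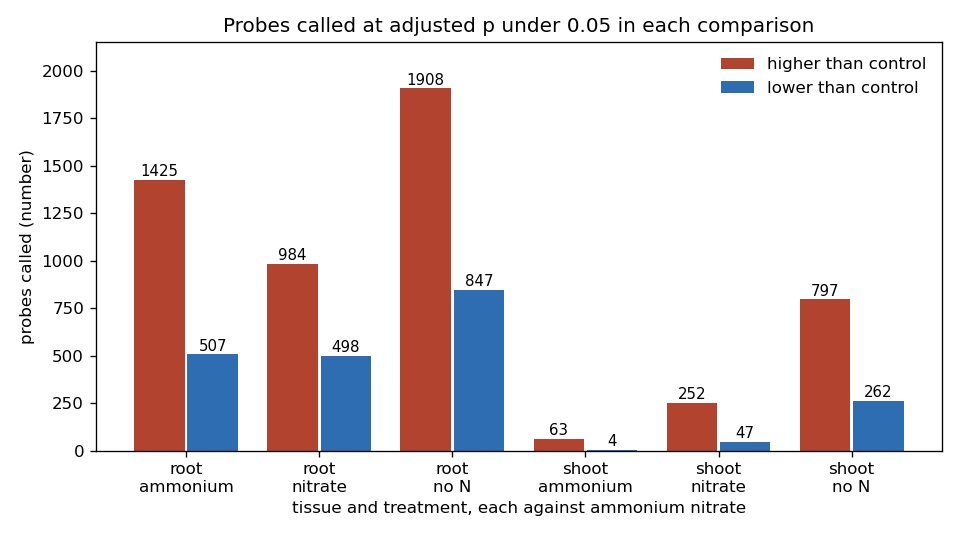
Number of probes called at adjusted p under 0.05 in each tissue and treatment against ammonium nitrate, higher in red and lower in blue, of 17860 tested. Roots without nitrogen have the most, 1908 higher and 847 lower, and shoots on ammonium the fewest, 63 and 4.

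Shoots on ammonium alone differed little from shoots on ammonium nitrate. PBZ1 rose by 1.34 (SE 0.0766, n = 2 arrays, adjusted p = 0.000553), the chitinase Cht11 (LOC4331519) by 1.11 (SE 0.0995, adjusted p = 0.00397) and the catalase CAT-A (LOC4328073) by 1.28 (SE 0.191, adjusted p = 0.0421). CHS (LOC4350636), the chalcone synthase that opens flavonoid synthesis, rose by 1.06, YSL13 (LOC4336441) by 1.03, OsNrx1-1 (LOC4333075) by 0.81, TBP1 (LOC4331151) by 0.71 with a second probe at -0.01, and GH3-8 (LOC4343785), which conjugates auxin to amino acids, by 0.65. The metallothionein MT2C (LOC4337596) fell by 1.17 and NIA1 by 1.08, with second probes at -0.15 and -0.20. Only these 2 named genes fell. The next 6 by p did not pass: DREB1G (LOC4330306, -0.67), MtN3-like (LOC4326923, -0.33), MRS2-A (LOC4333741, -0.27), D53-L (LOC4351252, -0.32), FDRMADS7 (LOC4343851, -0.29) and HOX24 (LOC4330155, -0.31), at adjusted p from 0.232 to 0.612.

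No probe of nitrate or ammonium transport or of ammonium assimilation was called in these shoots by limma, with AMT3-2 at 0.86 (adjusted p = 0.135) and GDH1 at 0.40 (adjusted p = 0.221). Adjusted over the list alone, 1 ammonium transporter and 1 assimilation probe rose. The 20 ribosomal protein probes had a median of 0.17 and shifted upward together with 0 of them called by limma and 0 adjusted over the list alone (camera adjusted p = 1.02e-06, adjusted p = 0.151 with an estimated correlation). RPL11 (LOC4338077) stood at 0.29. Of 15 pathogenesis-related probes 2 rose, or 3 adjusted over the list alone. Their adjusted p was 0.0095 (0.068 with the block within tissue, 0.0359 with the common block, 0.258 without replicate 2, 0.163 without array rows 1 to 40, adjusted p = 0.203 with an estimated correlation). The 19 phosphate starvation probes had a median of -0.01 but a mean of 0.13 and an upward test, with 0 called by limma, 3 adjusted over the list alone and 1 up with the replicate block. PHT1-8 stood at 0.95 (second probe -0.02) and SPX2 at 0.70. The list's adjusted p was 0.0251 (0.0567 with the replicate block, 0.104 without replicate 1, 0.122 without replicate 2, adjusted p = 0.151 with an estimated correlation). Expansins and related cell wall loosening proteins had a median of -0.08 over 33 probes, with 0 called by limma and 0 adjusted over the list alone. Their adjusted p was 0.0464 (0.0583 with the mean of a gene's probes, 0.215 without replicate 1, 0.177 without replicate 2, 0.0505 and 0.0549 without replicate 1 or 2 of the roots without nitrogen, 0.084 without array rows 1 to 40, adjusted p = 0.163 with an estimated correlation).

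In all, 63 probes rose and 4 fell in shoots on ammonium, with 797 at an unadjusted p under 0.05, and 104 rose and 4 fell with the replicate block. Without replicate 1 of this group 12 were called (9 up, 3 down) and without replicate 2, 9 (8 up, 1 down). Leaving out any 1 of the ammonium root arrays or of the 4 arrays without nitrogen left 1 or 2 falling probes. Of the 10 named genes that passed, 9 lost their call without 1 or the other array (adjusted p from 0.0554 to 0.724), and PBZ1 kept it. YSL13 and TBP1 did not pass with the replicate block (adjusted p = 0.0503 and 0.0833), and both, like NIA1, are read in array rows 1 to 40. Fitted with the shoot arrays alone, 0 probes passed in limma, with 608 at an unadjusted p under 0.05 against 797 in the fit of all arrays. After the swapped array was turned, the 2 arrays of this group correlated with r = -0.295 over genes, since the part that follows the dyes (SD 0.235) exceeded the part that follows the treatment (SD 0.174).

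The chalcone synthase CHS rose and the glutaredoxin GRXC1 fell in shoots on nitrate alone relative to shoots on ammonium nitrate. The lipid transfer protein LTP110-A (LOC4349601) rose by 2.97 (SE 0.429, n = 2 arrays, adjusted p = 0.0149), CHS by 1.83 (SE 0.142, adjusted p = 0.00092), and the ascorbate peroxidase APX7 (LOC4335896) by 1.89 (SE 0.176, adjusted p = 0.00207) with a second probe at 0.64. OsNrx1-1 (1.53), rab25 (LOC4326935, 1.51), the glycosyltransferase OsGT47D (LOC4327240, 1.46), SPX2 (1.42) and AT5 (LOC4338283, 1.31) followed. The glutaredoxin GRXC1 (LOC4325734) fell by 1.3 (SE 0.101, adjusted p = 0.00092). The small heat shock protein HSP18.0 (LOC4325342, -0.92, second probe 0.19), the response regulator RR9 (LOC4349747, -0.90), GRXC15 (LOC4352426, -0.85), MT2C (-0.68, second probe -0.20), GSTU6 (LOC4349207, -0.66, other probes -0.49 and -0.02), RR6 (LOC4337372, -0.54) and ILL2 (LOC4327677, -0.52) also fell.

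NIA1 rose by 1.16 in these shoots (adjusted p = 0.00924) and its second probe read 0.02. None of 3 nitrate transport probes was called by limma, also adjusted over the list alone, with NRT2.2 at -0.25 (adjusted p = 0.699). The 8 ammonium transporter probes shifted upward at a median of 0.12 with 0 called by limma and 2 up adjusted over the list alone or with the replicate block. AMT3-2 stood at 0.83 (adjusted p = 0.0556), and the list's adjusted p was 0.0464 (0.0722 with the replicate block, 0.0534 without replicate 1, 0.241 without replicate 2, 0.0586 to 0.0641 without any 1 of the 4 arrays without nitrogen, 0.0902 without array rows 1 to 40, adjusted p = 0.185 with an estimated correlation). Among 8 assimilation probes 0 were called by limma, against 2 up and 1 down adjusted over the list alone and 1 up with the replicate block, and GLN2 (LOC4337272), the plastid glutamine synthetase, stood at 0.46 (adjusted p = 0.101). Of 19 phosphate starvation probes 5 rose, also adjusted over the list alone, with PHT1-2 at 1.14 and PHT1-8 at 1.00, its second probe at 0.04 (camera adjusted p = 0.00483, adjusted p = 0.101 with an estimated correlation). Of 20 phenylpropanoid probes CHS and CAD6 (1.02) rose, or 6 adjusted over the list alone and 7 with the replicate block, where 1 fell (camera adjusted p = 0.00483, adjusted p = 0.101 with an estimated correlation). SGR (0.82) was the 1 of 7 senescence probes that rose, or 2 adjusted over the list alone or with the replicate block, with a list adjusted p of 0.0137 (0.163 without replicate 1, adjusted p = 0.151 with an estimated correlation). Iron genes rose at 3 of 26 probes, also adjusted over the list alone, YSL13 (1.07), the vacuolar iron transporter VIT1 (LOC4336075, 0.79) and Nramp1 (LOC4342862, 0.43), in a list that did not pass (adjusted p = 0.353).

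Type-A response regulators, which cytokinin induces, fell at 2 of 8 probes in shoots on nitrate, or 4 adjusted over the list alone (camera adjusted p = 9.48e-05, adjusted p = 0.101 with an estimated correlation). The 16 chlorophyll synthesis probes had a median of -0.12 with 0 called by limma, 0 adjusted over the list alone and 3 down with the replicate block, and PORB (LOC4349004) stood at -0.34 (adjusted p = 0.278). That list's adjusted p was 0.00483 (0.123 without replicate 1, adjusted p = 0.101 with an estimated correlation). The 20 ribosomal protein probes had a median of -0.15 with 0 called, 0 adjusted over the list alone and 1 down with the replicate block (camera adjusted p = 0.0042, adjusted p = 0.259 with an estimated correlation). The 17 probes of cyclins and a centromere histone had a median of -0.14 with 0 called by limma and 0 adjusted over the list alone. Their adjusted p was 0.0152 (0.0638 without replicate 1, 0.0937 without replicate 2, adjusted p = 0.185 with an estimated correlation). The light reactions (median -0.21) and the aquaporins (median 0.12) did not pass (adjusted p of 0.0882 and 0.051, adjusted p = 0.545 and 0.166 with an estimated correlation), nor with the common block (0.0702 and 0.0533). They passed in alternatives chosen for lists after the data were seen: with the block within tissue (0.0166 and 0.0344), the light reactions without replicate 2 (0.000544), and the aquaporins without any 1 of the ammonium or nitrate root arrays (0.0451 to 0.0484). In all 252 probes rose and 47 fell, and 674 rose and 193 fell with the replicate block. Without replicate 1 of this group 88 were called (74 up, 14 down) and without replicate 2, 107 (71 up, 36 down). Without either ammonium root array 197 were called (170 up, 27 down), and without either nitrate root array or either ammonium shoot array 30 fell. The shoot arrays fitted alone called 27. Of the 16 genes of highest and lowest ratio 10 lost their call without 1 or the other array (adjusted p from 0.0662 to 0.347), and CHS, OsNrx1-1, rab25, OsGT47D, APX7 and GRXC1 kept it. With the shoot arrays alone 13 of the 16 lost it, among them OsGT47D, APX7 and GRXC1, and only CHS, OsNrx1-1 and rab25 kept it. The calls of NIA1, YSL13, VIT1, Nramp1, PHT1-2, PHT1-8, SGR and CAD6 ended in that fit too. NIA1 (0.90) lost its call without replicate 2, and YSL13 (1.16 and 0.98), VIT1 (0.76 and 0.81), Nramp1 (0.48 and 0.38), PHT1-8 (1.21 and 0.80) and CAD6 (1.00 and 1.04) without either. NIA1, YSL13, AMT3-2 and GRXC15 are read in array rows 1 to 40. Turned, the 2 arrays correlated with r = -0.029 over genes.

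Between the 2 forms, shoots on ammonium had less NIA1 mRNA than shoots on nitrate, with a difference of -2.23 (SE 0.211, adjusted p = 0.0074) on the probe in array rows 1 to 40 and -0.22 on its second probe. rab25 (-1.83, adjusted p = 0.00333) and OsGT47D (-1.56, adjusted p = 0.0209) were lower too, and GRXC1 (1.3, adjusted p = 0.0133) and the zinc finger protein OsC3H2 (LOC4327304, 0.73, adjusted p = 0.0392) were higher on ammonium. The contrast called 9 probes higher and 32 lower, 28 and 56 with the replicate block, and 18 and 41 without array rows 1 to 40. Leaving out replicate 1 or 2 of the ammonium shoots left 12 and 15 calls, leaving out replicate 1 or 2 of the nitrate shoots 26 and 30 (the latter 13 higher and 17 lower), leaving out any 1 ammonium root array or array without nitrogen 25 to 27, and shoots fitted alone gave 0 (unadjusted p under 0.05 counted 737 in the fit of all arrays). With the shoot arrays alone 568 probes had an unadjusted p under 0.05 in limma, and none of these 5 genes kept its call. OsC3H2 lost it without any 1 of the 12 arrays (0.71 to 0.76). Without ammonium replicate 1 NIA1 (-2.11) and OsGT47D (-1.73) lost it, without ammonium replicate 2 NIA1 (-2.36), OsGT47D (-1.39) and GRXC1 (1.13), and without nitrate replicate 1 OsGT47D (-1.31) and GRXC1 (1.16). OsGT47D also lost it without any 1 of the ammonium root arrays or of the 4 arrays without nitrogen.

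Most of the ribosomal protein probes rose in shoots without nitrogen, 15 of 20 (camera adjusted p = 8.12e-20, adjusted p = 0.101 with an estimated correlation). LTP110-A rose by 3.26 (SE 0.429, n = 2 arrays, adjusted p = 0.00372), PAL06 by 2.39 (SE 0.293, adjusted p = 0.00282), CHS by 2.35 (SE 0.142, adjusted p = 0.000186), APX7 by 2.15 with a second probe at 0.44, the expansin EXPB3 (LOC4349349) by 2.03, CAD6 by 1.89, LTP2-B (LOC4351317) by 1.52 and RPL11 by 1.44. NAS2 fell by 3.34 (SE 0.429, adjusted p = 0.00338) and GRXC1 by 3.28 (SE 0.101, adjusted p = 5.68e-06). The kinesin KIN8B (LOC4334272, -2.34), the aquaporins PIP1-3 (LOC4331194, -1.64) and PIP2-5 (LOC4343121, -1.22), JAZ9 (-1.40), the recombinase DMC1 (LOC4351482, -1.26) and OsC3H2 (-1.22) fell as well.

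Of the 20 ribosomal protein probes none fell in these shoots, and 17 rose adjusted over the list alone. RPL7A-2 (LOC4347522) rose by 1.3, RPL5 (LOC4325100) by 1.13 and RPS4 (LOC4328016) by 1.11. Of 26 iron probes 4 fell and 1 rose, also adjusted over the list alone, with Nramp1 down by 1.2 on the log2 scale and VIT1 up by 1.14. The list's adjusted p was 0.0042 (0.0675 without replicate 2, adjusted p = 0.101 with an estimated correlation). Of 20 phenylpropanoid probes 6 rose, or 7 adjusted over the list alone (camera adjusted p = 0.00524, adjusted p = 0.101 with an estimated correlation). No nitrate transport or nitrate reduction probe was called by limma, also adjusted over the list alone. AMT1-2 rose by 1.00, the 1 of 8 ammonium transporter probes to do so, against 2 up and 2 down adjusted over the list alone and 1 and 1 with the replicate block. GDH1 rose by 0.67, the 1 of 8 assimilation probes called, against 3 up and 1 down adjusted over the list alone and 2 and 1 with the replicate block. NYC1 (1.2) and SGR (0.65) rose, 2 of 7 senescence probes, also adjusted over the list alone. Of 12 light reaction probes 3 fell, also adjusted over the list alone, the photosystem I subunits PSAG (LOC4337812, -0.58) and PSAH (LOC4339593, -0.56) and RCABP69 (LOC4343583, -0.48), while 3 of 16 chlorophyll synthesis probes rose, or 6 adjusted over the list alone and 5 with the replicate block, among them GSA (LOC4346136, 0.74, second probe -0.04) and GluTR (LOC4349044, 0.74). Neither of those lists passed (adjusted p of 0.147 and 0.0641), though the light reactions did without array rows 1 to 40 (0.0254, adjusted p = 0.58 with an estimated correlation over all array rows). Of 14 jasmonate ZIM-domain probes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone, with JAZ12 at 1.16 (camera adjusted p = 0.16).

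In shoots without nitrogen 797 probes rose and 262 fell, and 1474 rose and 761 fell with the replicate block. The array of replicate 1 read low along 1 edge. In its array rows 1 to 40, 33.2% of all features had a Cy5 over Cy3 log2 ratio below -1, against 3.03% elsewhere on it and 3.24% to 7.02% in the same place on the other 11 arrays. Without this array 357 probes were called, 293 up and 64 down. Without replicate 2 there were 1612, 426 up and 1186 down, so falls outnumbered rises when this array was the only one left. Without array rows 1 to 40 there were 1052, 794 up and 258 down. KIN8B stood at -3.64 on replicate 1 and -1.04 on replicate 2 and lost its call without replicate 1 (adjusted p = 0.173), as did LTP110-A (adjusted p = 0.0702), LTP2-B (adjusted p = 0.0515) and PIP2-5 (adjusted p = 0.127, and 0.163 without replicate 2). List members that lost their call without replicate 1 were GDH1 (0.61), PSAG (-0.57), PSAH (-0.49), RCABP69 (-0.57), NYC1 (0.96) and GSA (0.67), and without replicate 2 PSAG (-0.60), RCABP69 (-0.40) and GluTR (0.42). Fitted alone, the shoot arrays gave 354 calls (279 up, 75 down), and LTP110-A, LTP2-B, KIN8B, PIP1-3, PIP2-5, JAZ9, GDH1, PSAG, PSAH, RCABP69, GluTR and NYC1 lost theirs. KIN8B and PIP1-3 (-2.04 and -1.24) are read in those rows. Uncalled genes there had low ratios on replicate 1 alone, such as YSL14 (LOC9267947) at -3.64 against 0.05 and JAZ3 (LOC4345625) at -3.71 against 0.35.

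**Figure D2:**
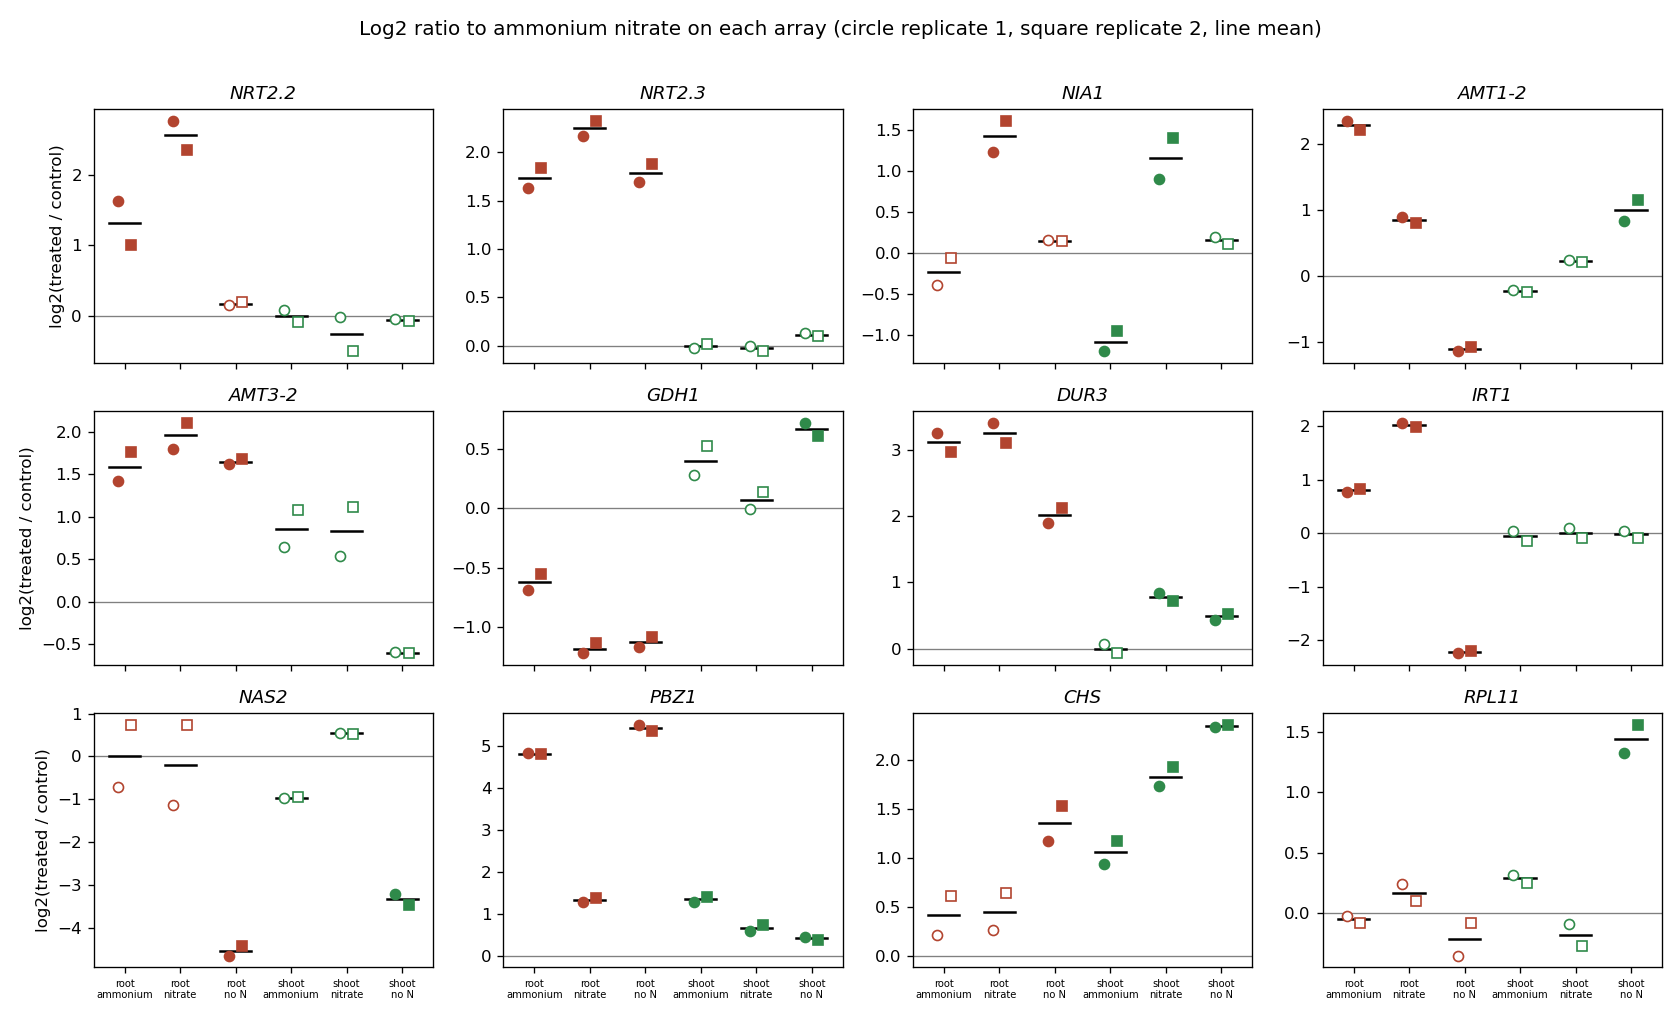
Log2 ratio to ammonium nitrate of 12 genes on each array, by tissue and treatment, with circles for replicate 1, squares for replicate 2 and a line at the mean. Filled symbols mark ratios that pass adjusted p under 0.05, and each panel has its own vertical scale. NIA1 is at 1.43 in roots and 1.16 in shoots on nitrate, and NAS2 at -4.54 and -3.34 without nitrogen.

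The responses of roots and shoots to the same treatment differed at many genes when the difference itself was tested. On ammonium PBZ1 was higher in roots by 3.49 (4.83 against 1.34), GLP2 by 3.43 (3.67 against 0.24) and DUR3 by 3.12 (3.12 against 0.00), while CML1 (-1.44), FIB (-1.32) and FH15 (-1.32) had negative differences, as they fell in roots (-1.31, -1.03 and -1.51) and stood at 0.13, 0.29 and -0.19 in shoots. On nitrate NRT2.2 (2.82), DUR3 (2.47) and MT1B (2.35) rose more in roots. OsNrx1-1 (-1.94) rose in shoots, at 1.53 against -0.41 in roots, while Lsi6 (-1.82, other probes -1.86 and -0.09) and TIP2-1 (-1.76) fell in roots, at -1.57 and -1.76 against 0.25 and 0.00 in shoots. Without nitrogen PBZ1 (5.03), the peroxidase LOC4344277 (4.96) and ICL (4.33) were higher in roots, with ICL at 0.00 in shoots. ILL3 (-4.27), NAS1 (-4.07) and LTP110-A (-3.65) had negative differences. ILL3 and NAS1 fell in roots (-4.19 and -4.33) and stood at 0.08 and -0.26 in shoots, and LTP110-A rose in shoots, standing at -0.39 in roots and 3.26 in shoots. All adjusted p of these genes lay between 1.02e-06 and 0.00601.

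The tissue contrast called 559 probes higher and 163 lower in roots on ammonium, 273 and 265 on nitrate, and 1256 and 1039 without nitrogen. With the replicate block these were 1109 and 577, 561 and 662, and 2108 and 1797. For ammonium, leaving out replicate 1 or 2 of the roots left 272 and 337 calls, leaving out shoot replicate 1 or 2 gave counts between these (254 and 255 higher, 49 and 48 lower), and FIB (-1.24) lost its call without shoot replicate 2. For nitrate the 4 fits without a root or shoot array gave 204, 241, 277 and 335, in the order root replicate 1 and 2, then shoot replicate 1 and 2. For no nitrogen the same order gave 1297, 1329, 1339 and 2615, the last with 1940 higher and 675 lower in roots. Over genes, root and shoot ratios correlated with r = 0.206 on ammonium, 0.225 on nitrate and 0.042 without nitrogen. The low edge of 1 shoot array may lower the last value. Both tissues shared 35, 110 and 187 rising probes, where independent lists would share 5.03, 13.9 and 85.1, and 0, 13 and 58 falling probes, against 0.114, 1.31 and 12.4. Probes called up in roots and down in shoots numbered 2, 5 and 55, where independent lists would share 0.319, 2.59 and 28.0. The reverse numbered 4, 17 and 83, against 1.79, 7.03 and 37.8, so calls in opposite directions exceeded the independent counts too.

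**Figure D3:**
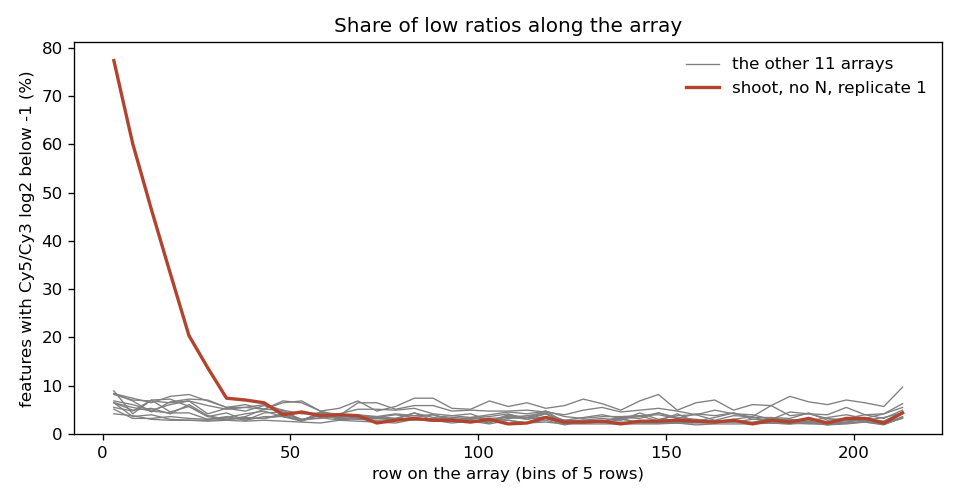
Percent of features with a Cy5 over Cy3 log2 ratio below -1 along the array, in bins of 5 array rows, for each of the 12 arrays. The array of shoots without nitrogen, replicate 1, starts at 77.3% and falls with distance from the edge, while the other 11 arrays stay low throughout.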

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

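The contrasts of roots minus shoots, leaving out each array and the fit of each tissue alone were chosen before the data were examined. The tests on features without a gene, on the edge of 1 array, on the spread in shoots and on the shared control were chosen after their results were seen.

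Roots and shoots differed in their response to the same treatment in tests of the difference itself. On ammonium 722 probes differed, among them PBZ1 (3.49), GLP2 (3.43), DUR3 (3.12), CML1 (-1.44), FIB (-1.32) and FH15 (-1.32). On nitrate 538 did, among them NRT2.2 (2.82), DUR3 (2.47), MT1B (2.35), OsNrx1-1 (-1.94), Lsi6 (-1.82) and TIP2-1 (-1.76). Without nitrogen 2295 did, among them PBZ1 (5.03), the peroxidase LOC4344277 (4.96), ICL (4.33), ILL3 (-4.27), NAS1 (-4.07) and LTP110-A (-3.65). These are log2 differences, roots minus shoots. Counts with 1 array left out are given below.

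Features that match no gene, which the comparisons did not use, also gave calls when all 22575 features were fitted: 178 of 4715 in roots on ammonium, 100 on nitrate and 209 without nitrogen, and 1, 28 and 97 in shoots. That is 3.78%, 2.12%, 4.43%, 0.0212%, 0.594% and 2.06% of them, lower in each group than the 10.3%, 7.68%, 14.6%, 0.342%, 1.59% and 5.63% of features with a gene.

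Fewer probes were called in shoots than in roots in each treatment. If the spread shared by both tissues had been the cause, roots fitted alone were predicted to have under 1.5 times the calls of shoots fitted alone in at least 1 treatment. The lowest ratio was 6.49, without nitrogen. The fit of shoots alone has fewer arrays and holds the array with the low edge, and both can lower its calls. The ratio therefore does not settle the question. A larger spread between shoot replicates could lower their counts: the median residual SD was 1.07 times that of roots without the no-nitrogen groups, too near 1 to decide. By treatment it was 0.189 in both tissues on ammonium. It was 0.187 in roots and 0.205 in shoots on nitrate, and 0.114 and 0.104 without nitrogen. The median was thus clearly larger in shoots only on nitrate. A smaller response of shoots is left as an untested hypothesis of the design's own 2 tissues. On ammonium the dye part was similar in both tissues (SD 0.225 in roots, 0.235 in shoots), while the treatment part was 0.42 in roots and 0.174 in shoots. The treatment part was lower in shoots on nitrate (0.258 against 0.362) and without nitrogen (0.451 against 0.514) too, and it includes noise.

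The array of shoots without nitrogen, replicate 1, read low along 1 edge. Its median log2 ratio of Cy5 over Cy3 was -2.70, -1.93 and -0.74 in array rows 1 to 5, 6 to 10 and 11 to 15, and 77.3% of features in rows 1 to 5 were below -1. Uneven hybridisation or scanning in a patch at the edge may account for it. Of 613 genes with probes both inside and outside array rows 1 to 40, 31.5% of probes inside were below -1 on this array and 0.878% of those outside, against 0.792% to 4.44% inside on the other arrays. The low readings thus followed the place and not the gene, which does not tell hybridisation from scanning and leaves the cause open. Whether the fault lowered only part of the features in the patch stays open: 40.5% of features without a gene in array rows 1 to 40 were below -1, against 10.3% to 14.4% on other arrays, where the prediction had asked for under 10%. Ammonium nitrate RNA in both channels, as the label reads, would leave no correlation with replicate 2, and outside array rows 1 to 40 r was 0.549 (bootstrap SD 0.017, 200 draws), against 0.151 inside. No biological explanation was tested for a position on the array.

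Root responses to the 3 treatments resembled each other, and error of the shared control RNA is a candidate explanation. Arrays of different replicate number should share none of it if each replicate had its own control extract, which the labels do not state. They also carry the dye part with opposite sign, which lowers their covariance where the dye part is shared. Their lowest covariance over the 3 pairs was 0.0665, above the 0.0384 to 0.0387 simulated for shared controls. This argues against control error as the whole of the resemblance only if that condition holds. A response common to the treatments remains a hypothesis.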

How the results depend on the processing

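The alternatives with all features, without array rows 1 to 40, with no array turned, for lists with a block within tissue or an array left out, and the direction over features with a gene were chosen after the data were seen. Where a result changed and no reason is given, the cause was not tested. Centring each array, robust eBayes, leaving out probes with an exact 0, all features and leaving out array rows 1 to 40 kept each total of calls within 1.5 times, while leaving out those array rows moved the probes higher in the shoot contrast of ammonium minus nitrate from 9 to 18. The alternative for missing values was not run, as no value is missing. The number of arrays, 2 per group, limits the precision, and signal over background was not analysed here.

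Scaling arrays to one median absolute deviation moved the root contrast of ammonium minus nitrate from 130 to 81 calls and roots minus shoots on ammonium from 722 to 450. It moved falling probes from 507 to 268 in roots on ammonium and from 262 to 446 in shoots without nitrogen. With the replicate block within tissue the calls became 3455, 2693 and 4329 in roots on ammonium, on nitrate and without nitrogen, 108, 867 and 2235 in shoots, 347 and 84 for ammonium minus nitrate in roots and shoots, and 1686, 1223 and 3905 for roots minus shoots. With the replicate block common to both tissues they were 3772, 2949 and 4552, then 183, 1148 and 2455, then 450 and 138, and 1931, 1461 and 4163. The block takes up the dye part, and the median probe SD falls from 0.205 to 0.137 and 0.136. Among the named genes of the 6 comparisons with the control, the block within tissue ended the calls of YSL13 and TBP1 in shoots on ammonium and of OSL2 in roots on nitrate. Apart from those and the list calls given in the report, it ended no other named call. Fitted with the arrays of 1 tissue, the root contrast gave 41 calls, shoots 0, 27 and 354, and the shoot contrast 0. Such fits have fewer arrays. Under 2-fold on both replicates in place of the test the counts were 461, 345 and 800 in roots, 32, 66 and 180 in shoots, 163 and 61 for ammonium minus nitrate in roots and shoots, up from 130 and 41, and 464, 400 and 1024 for roots minus shoots. This criterion drops small changes and asks for no test, so it lowered the other counts and raised those 2. With values as deposited and no array turned, calls were 0, 2 and 0 in roots, 0, 5 and 0 in shoots and 0 in each of the 5 contrasts, since the treatment part then cancels.

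Leaving out each array in turn gave 688 to 1853, 453 to 1397 and 1296 to 2690 calls in roots on ammonium, on nitrate and without nitrogen, 9 to 49, 88 to 237 and 357 to 1612 in shoots, 54 to 114 and 12 to 30 for the 2 contrasts of ammonium minus nitrate, and 272 to 652, 204 to 479 and 1297 to 2615 for roots minus shoots. Without replicate 2 of the shoots without nitrogen, falls outnumbered rises there. The lone array left in a group is then assumed to vary like the others. Of the 38 list calls 0 remained with an estimated correlation. With the replicate block within tissue 37 lists passed, 33 of them shared, with the common block 34, with the mean of a gene's probes 32, without array rows 1 to 40 39, and with 1 array left out 31 to 40. None of the 38 changed direction.

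Between arrays of opposite replicate number, correlations in roots fell to 0.325, 0.538 and 0.449 from 0.725, 0.66 and 0.586. In shoots they turned to -0.276 (ammonium and nitrate), -0.064 (ammonium and no nitrogen) and -0.014 (nitrate and no nitrogen) from 0.406, 0.133 and 0.119. Without array rows 1 to 40 the correlations of group means, which share their control, rose from 0.133 and 0.119 to 0.265 and 0.254 in the last 2 pairs. Correlations between opposite replicate numbers were not computed without those rows. The correlation of a group's 2 turned arrays over features with a gene was 0.558, 0.406 and 0.846 in roots and -0.295, -0.029 and 0.286 in shoots, against the opposite sign or a lower value over all features.

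Of 6168 values of passing named genes over the alternatives, 5580 kept their call, 588 lost it and 0 changed sign. In the comparisons with the control every called probe had the same sign on both arrays, so leaving out 1 array could not reverse it. Replicate blocks, robust eBayes and fits of 1 tissue change the spread and not the ratio. The absence of sign changes among called genes was thus largely fixed in advance. Uncalled genes that changed sign did so when 1 of their own 2 arrays was left out. They were, with lowest and highest value, OsRRA14 (-0.30, 1.71) and HSP24.1 (-0.38, 1.09) in roots on ammonium, CESA6 (-1.52, 0.28) and Cht5 (-1.05, 0.25) on nitrate and GST1 (-0.97, 0.04) without nitrogen, EXPA16 (-1.78, 0.06) in shoots on ammonium, PORA (-0.98, 0.13), CenH3 (-0.99, 0.05) and Chib3H-h (-0.06, 0.78) on nitrate, and YSL14 (-3.64, 0.05), ATG5 (-3.06, 0.02), CCR1 (-3.77, 0.24), JAZ3 (-3.71, 0.35), CESA8 (-1.86, 1.29), petC (-0.10, 0.43) and SPX3 (-0.71, 0.01) without nitrogen.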

Other observations

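The tests of this part were chosen in theme before the data were examined. The symbols in each list, and the added lists such as potassium transporters, were chosen after counts of calls were seen. Expansins and related wall-loosening proteins changed in both directions in roots. Of 33 probes 6 rose and 2 fell on ammonium, the same on nitrate, and 7 rose and 3 fell without nitrogen, or 6 and 3, 8 and 3, and 7 and 3 adjusted over the list alone. With the replicate block 5 fell on ammonium and 9 rose and 3 fell on nitrate. EXPA8 (LOC4327217) rose by 2.17, 1.97 and 0.94, EXPA3 (LOC4338278) by 2.1 and 2.00 on ammonium and nitrate, and EXPA4 (LOC4339106) and EXPA1 (LOC4335222) fell by 1.99 and 1.77 without nitrogen. The cellulose synthase CESA7 (LOC4348853) rose by 1.00, 1.37 and 0.90 in the 3 root groups, and CESA3 (LOC4343049) by 0.91 and 1.14 in shoots on nitrate and without nitrogen. No cellulose synthase of 13 probes fell in limma, against 2 in roots without nitrogen with the replicate block, and the list did not pass in the fit of all arrays (lowest adjusted p = 0.0741, in shoots without nitrogen, adjusted p = 0.298 with an estimated correlation), but did there without replicate 1 (0.0301). CESA3 lost both calls with the shoot arrays alone.

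Potassium transporters rose at 4 of 25 probes in roots on ammonium, 2 on nitrate and 4 without nitrogen, also adjusted over the list alone. With the replicate block 5 rose and 1 fell on nitrate. HAK1 (LOC4335729) stood at 2.15 and HAK16 (LOC4333298) at 1.62 on ammonium. HKT1.5 (LOC4327757), listed by its symbol and not by the ion it carries, stood at 1.68 on nitrate and 1.63 without nitrogen (lowest list adjusted p = 0.075). The small heat shock protein HSP17.9B (LOC4325695) rose by 2.07, 1.92 and 2.94 in the 3 root groups, in a list of 19 probes that passed nowhere (lowest adjusted p = 0.168). Glutathione transferase GSTU6 fell by 1.11 and 1.23 on nitrate and without nitrogen and rose by 0.59 on ammonium at the same probe, with 4 of 8 probes of its list up and 1 down on ammonium (lowest list adjusted p = 0.155). Of 26 Aux/IAA probes 3 rose and 3 fell in roots without nitrogen, or 6 and 3 with the replicate block, with IAA30 (LOC4352721) at -1.23 and IAA31 (LOC4352722) at -1.01 (lowest list adjusted p = 0.113). With all arrays and features no list passed for amino acid transport (lowest adjusted p = 0.43), ammonium assimilation (0.051), dehydrins and LEA proteins (0.274), glycolate oxidase and catalase (0.0726), light reactions (0.0882) or reductant supply to plastids (0.0745), where G6PGH2 (LOC4350528) rose by 0.76 in roots and 1.17 in shoots on nitrate. Alternatives chosen after the data were seen let some pass: in shoots on ammonium the light reactions without replicate 2 (0.00461) and glycolate oxidase and catalase without array rows 1 to 40 (0.0466), beside those of light reactions and ammonium assimilation given in the report. In shoots on ammonium, camera with an estimated correlation over all arrays gave these 2 lists an adjusted p of 0.65 and 0.203. Of the changes named here and above, HAK1 (2.55 and 1.74) lost its call without replicate 1 or 2 on ammonium. So did HKT1.5 (1.52 and 1.84, then 1.66 and 1.60) and IAA30 (-1.09 and -1.37) in the groups given, and CESA3 (0.83 and 0.98) in shoots on nitrate. EXPA4 (-1.33) lost it without replicate 1.

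The lists too short to test held few calls. The triose phosphate translocator TPT (LOC4326365) fell by 0.29, 0.50 and 0.48 in the 3 root groups, 1 of 3 carbon fixation probes, or 2 without nitrogen with the replicate block. Of 2 sulfate probes rcs1 (LOC4352839) fell by 1.06 in roots and 0.53 in shoots without nitrogen. Of 3 class III peroxidase probes, that of LOC4344277 rose by 2.12 and 1.63 in roots on ammonium and on nitrate as well (1.39 and not called on nitrate without replicate 1), PRX74 fell by 0.44 on ammonium as well as by 2.73 without nitrogen, and R1C-Prx (LOC4344045) by 0.37 on nitrate and 0.56 without nitrogen. The 2 smaller falls lost their call without replicate 1 or 2 (-0.34 and -0.54, -0.34 and -0.41) and with the root arrays alone. Of 4 fermentation probes PDC3 (LOC4344382) fell by 2.43 and Adh2 (LOC4350054) rose by 0.84 in roots without nitrogen, and both lost their call without either replicate (-2.1 and -2.76, 0.79 and 0.89). The root marker Lsi2 (LOC4331328) stood at -0.17, 0.00 and 0.25 in shoots, and 0 of the 2 root marker probes were called there by limma.

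In shoots 12 probes rose and 0 fell in all 3 treatments. The covariances between treatments there, 0.0182, 0.0104 and 0.0139, lay below the 0.0375 to 0.0379 simulated for groups sharing a control. The simulated values use 1 spread per probe, pooled over both tissues, and equal shares of control and treated RNA. They are not specific to shoots, so the lower covariances decide nothing about the shared control. The 4 arrays of the no-nitrogen groups stood apart from the other 8 in the dye part, which correlated at most 0.377 between them and the rest. Their median residual SD was 0.114 in roots and 0.104 in shoots, against 0.187 to 0.205 in the other groups. The dye parts of the 2 no-nitrogen groups correlated 0.155 with each other. The low edge of 1 shoot array enters that value, so it does not decide whether the 4 arrays formed 1 set. Median log2 ratios of Cy5 over Cy3 rose along the other 8 arrays. In the bin starting at array row 41 they lay from -0.188 to -0.098. In the bin starting at row 211 they lay from 0.198 to 0.352. On the 4 no-nitrogen arrays the medians lay from -0.016 to 0.028 and from -0.015 to 0.002 in these bins. These 4 arrays thus had in common that they lacked this rise.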
